A study of Homo sapiens with 24 samples.

How the data were processed

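Human cardiomyocytes derived from induced pluripotent stem cells (iCell) were left unstimulated or kept for 18 h with endothelin-1 and either vehicle or an inhibitor, per the labels. Libraries were amplicon libraries of a whole-transcriptome panel (Ion AmpliSeq), made from 20 ng of total RNA and pooled 14 to a pool, per the labels' protocols, and read on an Ion Proton. Which library was in which pool is not given in the labels, so no pool entered a fit. The deposited value for each gene was a CPM, per the file headers, and each library summed to 1e6 over 20812 symbols. The submitters' processing notes name the build hg19, and the aligner and counter are not given in the sources used here. No coordinate is printed.

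Within each library all CPM values were whole multiples of one step, 100.00% of them within 0.05 read, which gave back the reads behind them. Depth ran from 1492712 to 12292221 reads per library, and 3 reads, the floor used for a count, were worth more CPM in a shallow library. Intervals on ratios are 95% exact binomial intervals on reads summed over a group and cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The design fixed before the data were examined had a branch for counts and a branch for CPM. The CPM branch was used, and tests on the recovered reads were added as alternatives. Everything stated here as fixed was fixed before the data were examined, namely the groups, the main test, the other settings to be tried, the gene lists and the rule for naming genes.

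The main test was limma 3.58.1 in R 4.3.3, on log2(CPM + 1) for the 12943 genes with a mean of at least 1 CPM over the 24 libraries. All 6 groups entered one fit with empirical Bayes moderation, a mean-variance trend and robust settings, and calls had a two-sided Benjamini-Hochberg adjusted p under 0.05 within each comparison. The 10 comparisons were endothelin-1 with vehicle against unstimulated, each inhibitor against vehicle and against unstimulated, and importazole against ivermectin. Single genes were also tested between each pair of inhibitors. The replicates are not labelled as separate cultures, so the p-values measure the spread between these samples, which may be technical.

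Of 27 fixed gene lists, 26 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 26 lists. The lists were fetal and hypertrophy-associated genes, immediate early and SRF or MAPK response, sarcomere, calcium handling and ion channels, fatty acid oxidation, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, ATF4 targets, endoplasmic reticulum chaperones, NRF2 targets, heat shock, aryl hydrocarbon receptor targets, p53 targets, inflammatory response, interferon response, nuclear transport, cytoskeleton, lysosome and autophagy, cell cycle, and markers of fibroblasts and matrix, smooth muscle and pericytes, endothelium, epicardium and epithelium, nerve, pluripotent cells and hepatic endoderm.

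Genes were named by a fixed rule. It took a set of natriuretic peptide, myosin, actin, endothelin, channel, kinase and importin genes in every comparison. It added the 10 largest changes each way with endothelin-1, the 8 largest each way with each inhibitor and the 5 largest each way between importazole and ivermectin, among called genes of the genes above the median mean whose groups did not overlap. It also took up to 4 genes per list with at least 3 calls or past camera, and up to 10 genes that endothelin-1 moved and all 4 inhibitors moved back. A few genes that this rule took are not reported here. The share of the hormone's change that an inhibitor returned was a slope through the origin over genes chosen in 2 unstimulated and 2 vehicle libraries and measured in the rest, averaged over 36 choices. Overlaps of calls were set beside those of independent lists and those with the vehicle libraries split between the sides. Simulated unchanged groups gave no shared calls, so they say nothing about shared libraries and are not used here. Genes on the Y chromosome and XIST were not taken out of the fits or the counts of calls, but they were left out of the naming of genes.

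The fit was tested on simulated data with 200 changed genes per draw, over 5 draws. At 2-fold it recovered 72.2% of changed genes with endothelin-1, 67.2% with verapamil, 71.3% with importazole, 72.8% with IPA-3 and 71.9% with ivermectin, and calls on unchanged genes were 5.1%, 3.3%, 4.2%, 2.2% and 9.3% of calls. Other settings fixed beforehand were the replicate number as a block, a fit of the 2 groups alone, no filter, only genes above the median mean, quantile normalization, median centring, pseudocounts of 0.25 and 5, array weights, no trend, and each library left out in turn. Alternatives added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, reads thinned to the smallest library, a lowess correction for GC content with a span of 0.3, removal of the first component of the spread within groups, and leaving out the library of each group highest on that component. GC content came from GRCh38 transcripts, matched for 94.7% of the listed symbols. Splits of the 8 libraries of a comparison numbered 35 with the real one. Figures were drawn with Matplotlib 3.10.9 in Python 3.11.15.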

Results

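RNA was measured in cardiomyocytes derived from human induced pluripotent stem cells, bought as a commercial line (iCell), after 18 h with or without endothelin-1. Endothelin-1 is a peptide hormone used here at 10 nM to provoke hypertrophic growth. The 24 libraries fell into 6 groups of 4. These were unstimulated cells, endothelin-1 with vehicle (0.1% DMSO), and endothelin-1 with 1 of 4 inhibitors. The inhibitors were verapamil at 1 µM, a blocker of L-type calcium channels; importazole at 10 µM, an inhibitor of the nuclear import receptor importin-β; IPA-3 at 10 µM, an inhibitor of the kinase PAK1; and ivermectin at 3 µM, which blocks import by importin-α/β. Each library held between 1492712 and 12292221 reads over 20812 listed genes. Levels are given in CPM as mean ± SD over the 4 libraries of a group (n = 4), and changes as log2 differences ± standard error with limma's adjusted p over 12943 tested genes.

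Endothelin-1 with vehicle was compared with unstimulated cells to ask which genes the hormone changed. The skeletal actin gene ACTA1, a gene of the fetal heart program, rose from 845 ± 216 to 4558 ± 640 CPM, a change of 2.45 ± 0.21 (adjusted p = 2.25e-08). NPPB, which encodes the natriuretic peptide BNP, rose from 1905 ± 502 to 8647 ± 545 CPM (2.22 ± 0.20, adjusted p = 6.96e-08). NPPA, the gene of its atrial counterpart, rose by 0.36 ± 0.08 from 17050 ± 1070 to 21830 ± 613 CPM (adjusted p = 7.75e-04). The chemokine gene CCL3L3 went from 8.08 ± 1.94 to 403.3 ± 96.1 CPM (5.48 ± 0.19), and its near-identical copy CCL3 rose by 3.78 ± 0.34, with the split of reads between them uncertain. CCL4 had 1 read in all unstimulated libraries and 1143 with endothelin-1, a ratio of 562 with a 95% counting interval from 101 to 22200. ATP1B4, a muscle protein related to sodium pump subunits, rose from 34.59 ± 6.45 to 226.3 ± 6.75 CPM, a change of 2.69 ± 0.17.

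Of 20 fetal and hypertrophy-associated genes tested, 12 rose and 3 fell (camera adjusted p = 1.85e-11). They included CSRP3, a mechanosensor of the Z-disc (1.18 ± 0.11), XIRP1 (1.13 ± 0.10) and the stress-response gene ANKRD1 (0.63 ± 0.16). MYH7 stood at -0.09 ± 0.10 (adjusted p = 0.609), and MYH6 fell by 0.43 ± 0.14 with an adjusted p of 0.0396 that 14 of its alternatives moved past the threshold. The calcineurin reporter RCAN1 (0.31 ± 0.21) and EDN1, the endothelin-1 gene itself (0.39 ± 0.26), did not pass the test. EDNRA, the endothelin A receptor, fell by 0.80 ± 0.14 (adjusted p = 4.46e-05). Of 29 immediate early and MAPK-response genes, 14 rose and none fell, among them ETV4 (1.73 ± 0.16), FOSL2 (1.33 ± 0.15) and DUSP6 (1.17 ± 0.12). The cytoskeleton list had 9 of 34 higher and 2 lower, with FLNC at 1.44 ± 0.09 and RHOB at -0.87 ± 0.16. Heat shock genes were higher for 4 of 19 and lower for none, HSPA8 at 0.70 ± 0.10. Calcium handling and ion channel genes went down, 11 of 26, including RYR2 (-0.80 ± 0.14) and the pacemaker channel HCN4 (-0.45 ± 0.10). The 28 sarcomere genes had 4 up and 4 down. Their camera adjusted p was 0.0282 and the adjusted p = 0.249 with an estimated correlation.

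Among the largest single changes, the integrin ITGA4 (2.41 ± 0.23), CACNG4 (2.83 ± 0.27) and CAMK2N1 (2.39 ± 0.20) rose. SFRP5 (-2.19 ± 0.27), IGSF9 (-2.15 ± 0.22), the atrial gap junction gene GJA5 (-1.86 ± 0.33) and the fatty acid transporter SLC27A6 (-1.77 ± 0.16) fell. In glucose metabolism HK2 rose by 1.77 ± 0.14 and ALDOC fell by 1.01 ± 0.13. Genes that mark other cell types moved as well. Of 6 epicardial and epithelial markers 3 rose, KRT19 by 1.40 ± 0.18 and KRT18 by 1.28 ± 0.11, and of 7 neural markers 3 rose, TUBB3 by 0.81 ± 0.12 and NES by 0.67 ± 0.11. CACNA1C (0.53 ± 0.24), PAK1 (-0.18 ± 0.15) and KPNB1 (0.19 ± 0.12), targets or near targets of the inhibitors, did not pass the test. In total 1791 genes were called, 578 higher and 1213 lower, of which 313 changed at least 2-fold. The higher share was 32.3% here and 50.8% after each library was centred on its median, because the median of all tested genes lay at -0.10. The labels give no vehicle for unstimulated cells, so whether DMSO differed along with the hormone is not known. A DMSO percentage is given for the vehicle group only, so whether DMSO differed between vehicle and the inhibitor groups is not known either.

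**Figure D1:**
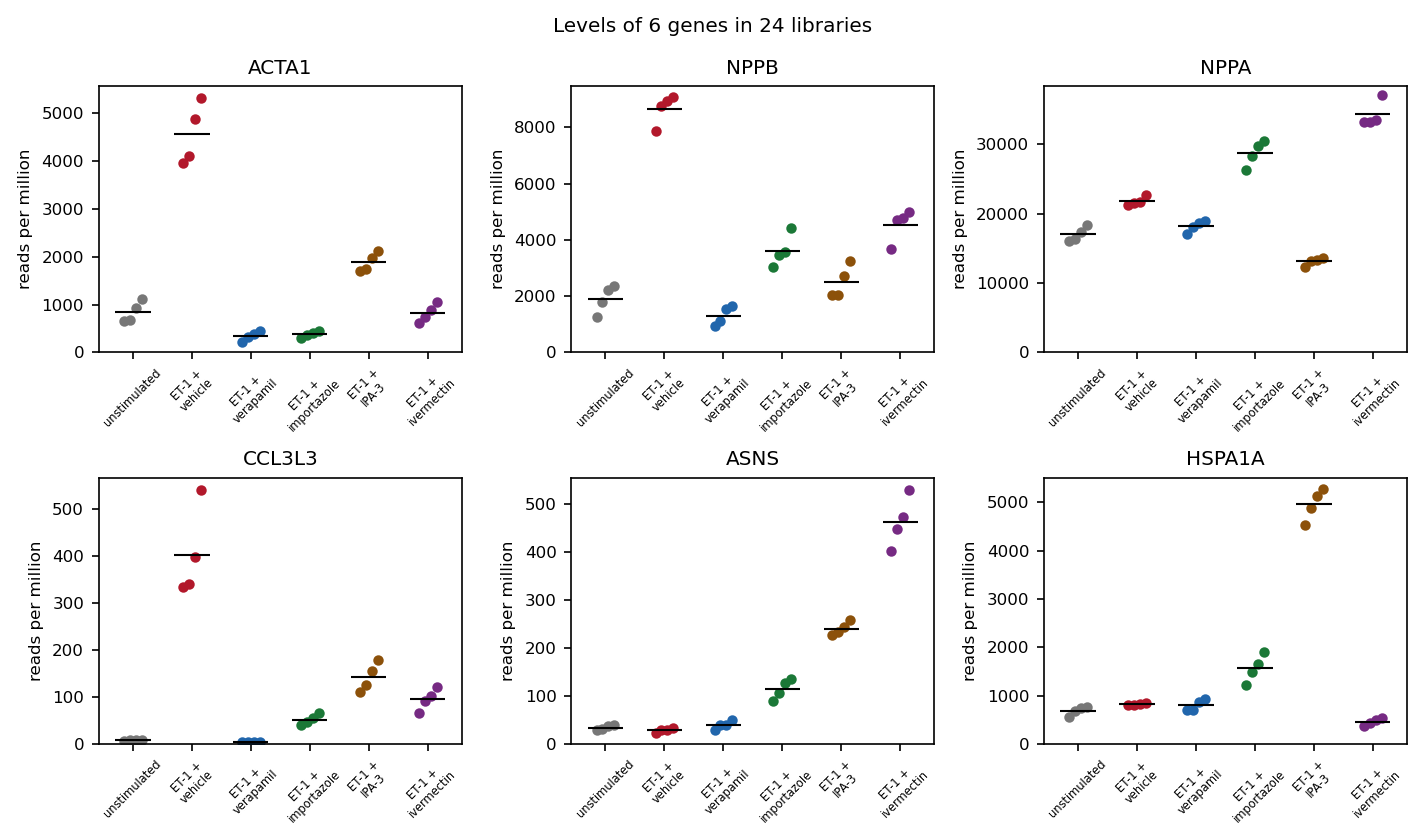
Levels in CPM (vertical axes, linear from 0) of 6 genes in each of the 24 libraries, by group; points are libraries and bars are group means of 4. ACTA1 averaged 4558 with endothelin-1 and vehicle against 336.1 with verapamil added, while NPPA was lowest with IPA-3 at 13140, an order that quantile normalization turned around (0.37 against vehicle on the log2 scale).

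Verapamil was set against vehicle, both with endothelin-1, to ask what blocking calcium entry did to the hormone's effect. The median of all tested genes was 0.14 higher with verapamil, so the main values are also given relative to that median. ACTA1 fell from 4558 ± 640 to 336.1 ± 96 CPM (-3.80 ± 0.21, adjusted p = 9.18e-12; -3.94 relative to the median). NPPB fell from 8647 ± 545 to 1307 ± 340 CPM (-2.76 ± 0.20; -2.90 relative to the median), and NPPA fell by 0.26 ± 0.08 (-0.40 relative to the median). CCL3L3 fell from 403.3 ± 96.1 to 3.687 ± 0.839 CPM (-6.42 ± 0.19; -6.56 relative to the median). CCL4 went from 1143 reads to 1, which is 965 times fewer with a 95% counting interval from 173 to 38100. ATP1B4 (-3.47 ± 0.17), the myofibril assembly gene NRAP (-3.15 ± 0.19), KRT80 (-3.04 ± 0.23) and CACNG4 (-3.04 ± 0.27) fell. CD226 (2.62 ± 0.27), FAM83B (2.25 ± 0.24), the glutamate transporter SLC1A1 (2.21 ± 0.26) and ROBO1 (1.93 ± 0.12) rose.

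The fetal and hypertrophy-associated list had 15 genes lower and 2 higher of 20 (camera adjusted p = 1.95e-21), with CSRP3 at -2.25 ± 0.11, CRYAB at -1.13 ± 0.11 and XIRP1 at -1.0 ± 0.10. ANKRD1 (-0.98 ± 0.16) and MYH7 (-0.65 ± 0.10) fell, whereas MYH6 (0.32 ± 0.14) and RCAN1 (-0.37 ± 0.21) did not pass the test. Sarcomere genes were lower for 14 and higher for 3 of 28, led by TCAP (-1.83 ± 0.13), TNNI3 (-1.38 ± 0.11) and ACTC1 (-1.02 ± 0.11). Immediate early genes were lower for 17 of 29 and higher for none, such as ETV4 (-1.63 ± 0.16) and DUSP5 (-1.09 ± 0.12). FLNC (-1.52 ± 0.09) was among 9 of 34 cytoskeleton genes that fell, with 2 higher. Heat shock genes fell for 4 of 19, HSPB1 by 0.98 ± 0.13, and oxidative phosphorylation genes for 4 of 38, with none higher in either list. Calcium handling and ion channel genes rose for 11 of 26 and fell for 2, with CACNB2 at 0.93 ± 0.14 and GJA1 at 0.90 ± 0.10. CACNA1C, the channel that verapamil blocks, stood at 0.17 ± 0.24.

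Chaperones of the endoplasmic reticulum rose for 17 of 20 genes, led by CALR (1.60 ± 0.13), PDIA4 (1.51 ± 0.16) and HSP90B1 (1.11 ± 0.11). Cell cycle genes rose for 10 of 22, with RRM2 at 1.75 ± 0.28, TOP2A at 1.68 ± 0.32 and TYMS at 1.06 ± 0.15. ATF4 targets, the genes of the integrated stress response, rose for 16 of 29, PHGDH by 1.08 ± 0.15 and PSAT1 by 0.88 ± 0.13. That list had a camera adjusted p of 1.8e-05 and an adjusted p = 0.155 with an estimated correlation. EDNRA rose by 0.42 ± 0.14 (adjusted p = 0.0282), a call that 11 alternatives lost. Markers of other cell types moved here too. Smooth muscle and pericyte markers had 5 of 12 lower, with CNN1 at -1.88 ± 0.12, and 4 higher (adjusted p = 0.0613 with an estimated correlation). Of 4 endothelial markers 1 fell (adjusted p = 0.0613 with an estimated correlation), of 6 epicardial markers 3 fell and 1 rose, KRT19 at -1.47 ± 0.18, and of 7 neural markers 3 fell. In all 2386 genes were called, 1701 higher and 685 lower. The higher share of 71.3% became 45.1% with median centring.

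Importazole was compared with vehicle to ask what an inhibitor of importin-β changed. ACTA1 fell to 379.1 ± 67.8 CPM (-3.59 ± 0.21, adjusted p = 1.91e-11) and NPPB to 3618 ± 576 CPM (-1.27 ± 0.20, adjusted p = 3.75e-05), while NPPA rose to 28750 ± 1860 CPM (0.40 ± 0.08, adjusted p = 6.2e-05). The amino acid synthesis genes PSAT1 and ASNS rose from 38.1 ± 5.3 to 184.9 ± 11.9 CPM and from 28.64 ± 3.68 to 113.9 ± 20.2 CPM (2.26 ± 0.13 and 1.95 ± 0.14). HSP90B1, a chaperone of the endoplasmic reticulum, rose from 741.4 ± 29.9 to 2258 ± 267 CPM (1.60 ± 0.11). TFPI2, an inhibitor of proteases in the matrix, rose by 3.43 ± 0.22, and KRT80 (-3.91 ± 0.23), ITGA4 (-2.83 ± 0.23) and the actin-binding activator ABRA (-2.79 ± 0.30) fell. CCL3L3 fell by 2.94 ± 0.19.

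ATF4 targets rose for 26 of 29 genes with a median of 1.17, among them TRIB3 (2.08 ± 0.15). Endoplasmic reticulum chaperones rose for 18 of 20 with a median of 1.10, HERPUD1 by 1.82 ± 0.15. Heat shock genes rose for 13 of 19, including HSPH1 (1.03 ± 0.10) and HSPA1A (0.91 ± 0.12), but HSPB1 fell by 1.61 ± 0.13. NRF2 targets rose for 12 of 23, HMOX1 by 1.09 ± 0.14 (adjusted p = 0.363 with an estimated correlation). Cholesterol synthesis genes rose for 10 of 24 and fell for 2, with CYP51A1 at 1.44 ± 0.15 and MSMO1 at 0.94 ± 0.12 (adjusted p = 0.331 with an estimated correlation). Lysosome and autophagy genes rose for 10 of 24 and fell for 1 (adjusted p = 0.15 with an estimated correlation).

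Fetal genes fell for 13 of 20 and rose for 1, with MYH7 at -0.96 ± 0.10 and XIRP1 at -0.88 ± 0.10, while MYH6 rose by 0.45 ± 0.14 and ANKRD1 stood at -0.25 ± 0.16. RCAN1 fell by 0.71 ± 0.21. Sarcomere genes fell for 14 of 28 and rose for 4, TCAP at -1.97 ± 0.13 and ACTC1 at -1.54 ± 0.11. Cytoskeleton genes fell for 18 of 34 and rose for 2, and oxidative phosphorylation genes fell for 19 of 38 and rose for 5, such as UQCRC1 (-1.17 ± 0.17) and COX4I1 (-0.82 ± 0.12). Of the import machinery, KPNB1, which encodes importin-β, fell by 0.58 ± 0.12 (adjusted p = 2.88e-04), while KPNA2 (-0.05 ± 0.11) and RAN (-0.07 ± 0.10) did not pass the test. The exporters XPO1 (2.44 ± 0.40) and XPOT (1.30 ± 0.11) rose, in a nuclear transport list that had a median of -0.02 and did not pass camera. Both also rose with IPA-3 and ivermectin, XPO1 by 2.67 and 1.27 and XPOT by 1.21 and 2.28. Immediate early genes went both ways, 9 up and 7 down of 29, with DUSP1 at 0.97 ± 0.16 and IER3 at -2.09 ± 0.16. Smooth muscle and pericyte markers fell for 9 of 12, CNN1 at -2.09 ± 0.12, DES at -1.90 ± 0.13 and TAGLN at -1.22 ± 0.12. CNN1 and DES are also in the cytoskeleton list and TAGLN in the fetal list, so this fall need not come from other cell types. Epicardial markers fell for 3 of 6, KRT8 at -1.77 ± 0.17, neural markers for 3 of 7, TUBB3 at -1.55 ± 0.12, and endothelial markers for 2 of 4 (adjusted p = 0.0509 with an estimated correlation).

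In total importazole changed 4705 genes, 2927 higher and 1778 lower, with 991 at least 2-fold. The higher share of 62.2% became 46.4% with median centring. Genes such as EXOC5 (3.13 ± 0.44), TECRL (3.40 ± 0.41) and EIF2S2 (2.96 ± 0.41) rose together and varied between replicates. The log2 change fell with the GC content of the transcript, with a Spearman rho of -0.30 across genes, which are not independent replicates. It was 0.03 for endothelin-1 alone, -0.11 for verapamil, -0.23 for IPA-3 and -0.24 for ivermectin.

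IPA-3 was compared with vehicle to ask what an inhibitor of PAK1 changed. The heat shock genes HSPA6 and HSPA1A rose from 116.1 ± 12 to 1187 ± 89.4 CPM (3.35 ± 0.18, adjusted p = 1.06e-13) and from 821.7 ± 26.8 to 4955 ± 319 CPM (2.59 ± 0.12, adjusted p = 9.31e-21). ASNS rose to 240.1 ± 13.1 CPM (3.03 ± 0.14) and HSP90B1 to 3945 ± 457 CPM (2.40 ± 0.11). ACAT2, an enzyme of cholesterol synthesis, fell from 217.4 ± 19.4 to 75.43 ± 3.38 CPM (-1.51 ± 0.11, adjusted p = 1.74e-14). NPPB fell to 2515 ± 582 CPM (-1.81 ± 0.20) and ACTA1 to 1880 ± 192 CPM (-1.27 ± 0.21). NPPA fell to 13140 ± 544 CPM (-0.73 ± 0.08), but its change was 0.37 after quantile normalization.

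Heat shock genes rose for 17 of 19 and fell for 1, with a median of 1.62. HSP90AA1 (2.57 ± 0.12), HSPD1 (2.37 ± 0.09), HSPH1 (2.28 ± 0.10) and CRYAB (1.77 ± 0.11) were among them. Endoplasmic reticulum chaperones rose for 20 of 20, PDIA4 by 2.30 ± 0.16, and ATF4 targets rose for 25 of 29 and fell for 1, with PSAT1 at 2.50 ± 0.13 and SLC3A2 at 2.15 ± 0.11. Cholesterol synthesis genes fell for 20 of 24 and rose for 1, including INSIG1 (-2.07 ± 0.20), DHCR7 (-1.49 ± 0.12) and IDI1 (-1.24 ± 0.11). Oxidative phosphorylation genes fell for 26 of 38 and rose for 4, ATP5G1 at -1.14 ± 0.12 and COX8A at -1.06 ± 0.11. Fatty acid oxidation genes fell for 11 of 27 and rose for 5.

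Sarcomere genes were lower for 20 of 28 and higher for 2, with TCAP at -2.09 ± 0.13, TNNC1 at -1.56 ± 0.11 and ACTC1 at -1.54 ± 0.11. Calcium handling genes were lower for 14 of 26 and higher for 2, including calsequestrin CASQ2 (-1.90 ± 0.16), TRDN (-1.07 ± 0.11) and HRC (-1.04 ± 0.10). The fetal list had 16 lower and 3 higher of 20, with MYH7 at -1.84 ± 0.10, RCAN1 at -1.07 ± 0.21, ANKRD1 at -0.46 ± 0.16 and XIRP1 at -0.27 ± 0.10, whose adjusted p of 0.0331 was lost under 9 alternatives. MYH6 stood at -0.20 ± 0.14. C10orf71, a muscle gene, fell by 2.87 ± 0.18 and the epoxygenase CYP2J2 by 2.11 ± 0.14. LAMP3 (3.38 ± 0.30), SERPINE2 (3.30 ± 0.26) and the replication licensing gene CDC6 (2.93 ± 0.21) rose. The cytoskeleton list went both ways, 9 up and 14 down of 34, with FLNC at 1.34 ± 0.09 and ACTB at 1.00 ± 0.09 up. PAK1 (0.26 ± 0.15) and PAK2 (0.06 ± 0.14) did not pass the test.

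Nuclear transport genes rose for 14 of 44 and fell for 3 (camera adjusted p = 0.0475, adjusted p = 0.0946 with an estimated correlation). The inflammatory list had 7 of 12 higher and 3 lower, NFKB2 by 1.49 ± 0.18, BIRC3 by 1.69 ± 0.28 and VCAM1 at -0.74 ± 0.11, and did not pass camera (adjusted p = 0.615). FOS rose by 1.85 ± 0.22, and CCL4 fell by 3.37 ± 0.33. Smooth muscle and pericyte markers fell for 10 of 12, among them DES (-1.96 ± 0.13), CNN1 (-1.30 ± 0.12) and RGS5 (-1.03 ± 0.10). Fibroblast and matrix markers fell for 5 of 13 (adjusted p = 0.0721 with an estimated correlation). The IPA-3 libraries held 5476104 to 11274194 reads each. IPA-3 changed 5644 genes, 3361 higher and 2283 lower, with 1365 at least 2-fold. The higher share of 59.5% became 47.5% with median centring.

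Ivermectin was compared with vehicle to ask what blocking importin-α/β changed. The median of all tested genes was 0.11 higher with ivermectin. PSAT1 rose from 38.1 ± 5.3 to 574.8 ± 47 CPM (3.89 ± 0.13, adjusted p = 1.04e-25; 3.78 relative to the median) and ASNS from 28.64 ± 3.68 to 462.7 ± 53.2 CPM (3.97 ± 0.14, adjusted p = 3.58e-25; 3.86 relative to the median). ACAT2 fell from 217.4 ± 19.4 to 74.55 ± 9.1 CPM (-1.54 ± 0.11; -1.65 relative to the median). ACTA1 fell to 822.7 ± 185 CPM (-2.49 ± 0.21; -2.60 relative to the median) and NPPB to 4543 ± 591 CPM (-0.94 ± 0.20; -1.05 relative to the median). NPPA rose to 34330 ± 1910 CPM (0.65 ± 0.08; 0.54 relative to the median). HSPA1A fell to 461.4 ± 68.4 CPM (-0.84 ± 0.12; -0.95 relative to the median).

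All 29 tested ATF4 targets rose, with a median of 2.02 (camera adjusted p = 1.1e-36). PCK2 (3.89 ± 0.17), the glutathione-degrading enzyme CHAC1 (3.42 ± 0.16), the nutrient sensor SESN2 (3.37 ± 0.12) and the stress hormone GDF15 (2.38 ± 0.21) rose, as did BCAT1 (3.58 ± 0.22), ALDH1L2 (3.57 ± 0.26) and LAMP3 (3.44 ± 0.30). Cholesterol synthesis genes fell for 21 of 24 and rose for 1, with IDI1 at -1.47 ± 0.11, MVK at -1.29 ± 0.12 and EBP at -1.19 ± 0.11. Endoplasmic reticulum chaperones rose for 16 of 20, XBP1 by 1.65 ± 0.11 and HERPUD1 by 1.64 ± 0.15 (adjusted p = 0.164 with an estimated correlation). Heat shock genes fell for 8 of 19 and rose for 2, HSPB1 at -1.63 ± 0.13. Oxidative phosphorylation genes fell for 24 of 38 and rose for 3, including COX4I1 (-1.11 ± 0.12) and ATP5G3 (-0.96 ± 0.10).

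Cytoskeleton genes fell for 21 of 34 and rose for 2, with vinculin (VCL) at -1.82 ± 0.14. KRT80 (-3.56 ± 0.23), ABRA (-3.09 ± 0.30) and PLA2G3 (-2.80 ± 0.25) fell, and CCL4 fell by 4.58 ± 0.33. The fetal list had 14 lower and 1 higher of 20, with FHL2 at -1.21 ± 0.12, XIRP1 at -1.15 ± 0.10, RCAN1 at -0.81 ± 0.21 and MYH7 at -0.68 ± 0.10. ANKRD1 (-0.34 ± 0.16) did not pass the test, and MYH6 changed by less than its standard error of 0.14. Sarcomere genes fell for 16 of 28 and rose for 2, ACTC1 at -1.73 ± 0.11 and TCAP at -1.31 ± 0.13. The channel genes KCNJ2 (1.70 ± 0.21) and GJA1 (1.51 ± 0.10) rose in a list that did not pass camera (9 up, 5 down of 26). KPNB1 (-0.57 ± 0.12), KPNA2 (-0.56 ± 0.11) and RAN (-0.27 ± 0.10) fell, the last a call that 7 alternatives lost, and the tRNA exporter XPOT rose by 2.28 ± 0.11. Smooth muscle and pericyte markers fell for 9 of 12, CNN1 at -2.02 ± 0.12, DES at -1.52 ± 0.13 and TAGLN at -1.08 ± 0.12. The ivermectin libraries held 1670784 to 2081913 reads each. Ivermectin changed 5538 genes, 3419 higher and 2119 lower, with 1158 at least 2-fold. The higher share of 61.7% became 49.8% with median centring, and on simulated data 9.3% of this comparison's calls were on unchanged genes.

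**Figure D2:**
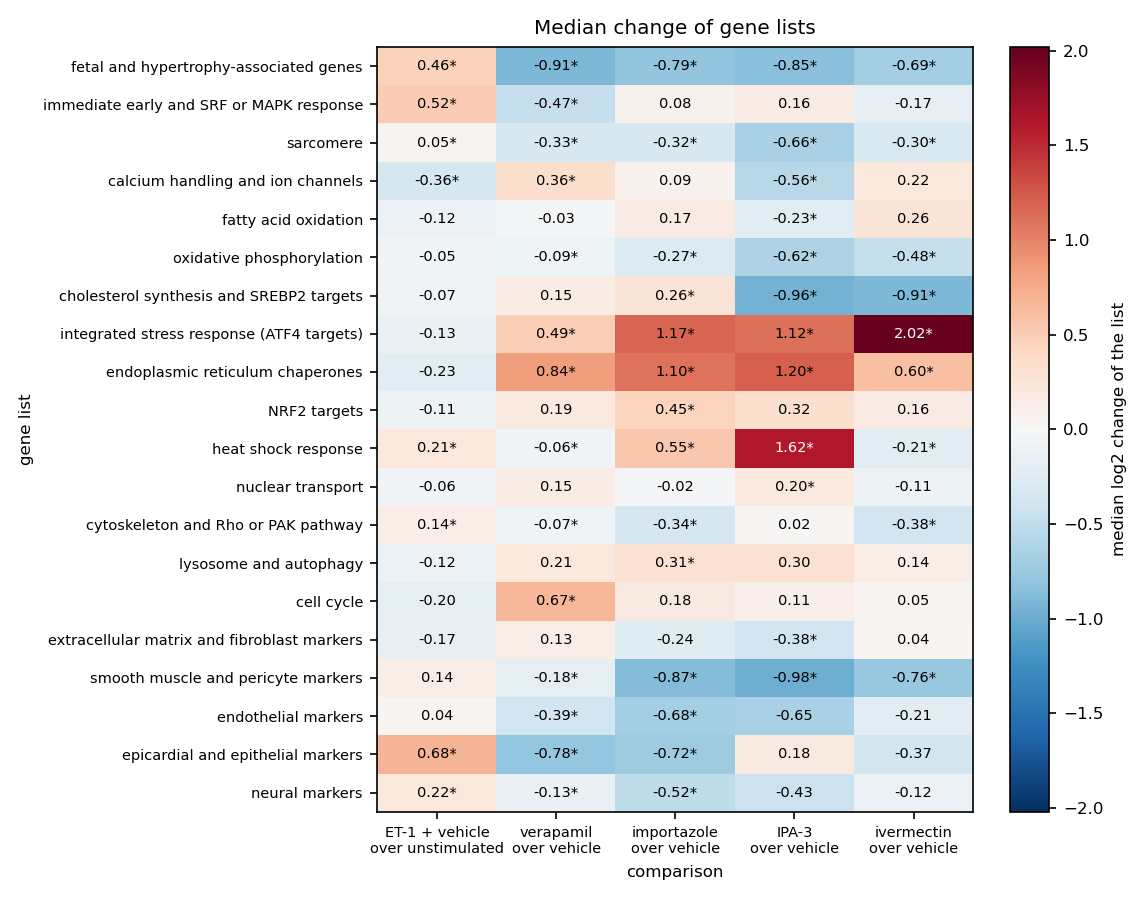
Median log2 change (cell values and colour) of the gene lists that passed camera in at least 1 of 5 comparisons (columns), with asterisks where camera's adjusted p was under 0.05. ATF4 targets had medians of 1.17, 1.12 and 2.02 with importazole, IPA-3 and ivermectin, and cholesterol genes of 0.26, -0.96 and -0.91.

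Importazole and ivermectin, both inhibitors of nuclear import, were compared with each other. ACAT2 was higher with importazole, 298.1 ± 19.7 against 74.55 ± 9.1 CPM (1.99 ± 0.11, adjusted p = 3.01e-17). ASNS was lower with importazole (-2.02 ± 0.14, adjusted p = 6.05e-15), and HSPA1A was higher, 1563 ± 289 against 461.4 ± 68.4 CPM (1.75 ± 0.12, adjusted p = 7.35e-15). Cholesterol synthesis genes were higher with importazole for 21 of 24 and lower for none, among them INSIG1 (2.31 ± 0.20), HMGCS1 (1.74 ± 0.12) and IDI1 (1.66 ± 0.11). Outside that list TMEM97 (2.10 ± 0.12) was higher too. ATF4 targets were lower for 25 of 29 and higher for none, such as PCK2 (-2.06 ± 0.17), SESN2 (-1.94 ± 0.12) and PSAT1 (-1.63 ± 0.13). Heat shock genes were higher for 13 of 19, with HSPA1B, a near copy of HSPA1A, at 1.87 ± 0.17 and HSPH1 at 1.40 ± 0.10.

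Oxidative phosphorylation genes were higher with importazole for 7 of 38 and lower for 1. Endoplasmic reticulum chaperones were higher for 9 of 20 and lower for 1, HSP90B1 by 1.08 ± 0.11, with XBP1 at -0.78 ± 0.11 in the other direction. Glycolysis genes were higher for 8 of 29, ALDOC by 1.28 ± 0.13, and lower for 3, and lysosome genes were higher for 6 of 24 and lower for 1. The chaperone, glycolysis and lysosome lists each had an adjusted p = 0.122 with an estimated correlation. ARG2 (-2.23 ± 0.15), GPT2 (-2.08 ± 0.19), CD226 (-2.66 ± 0.27) and ALDH1L2 (-2.19 ± 0.26) were lower with importazole, and PLA2G3 (2.37 ± 0.25) was higher. ACTA1 was lower with importazole (-1.11 ± 0.21), as was NPPA (-0.26 ± 0.08), whose adjusted p of 0.0175 was lost under 8 alternatives. NPPB (-0.33 ± 0.20), XIRP1 (0.27 ± 0.10) and KPNB1 did not pass the test, KPNB1 with an adjusted p of 0.996. KPNA2 was higher by 0.51 ± 0.11, and MYH6 by 0.46 ± 0.14 with an adjusted p of 0.0299 that 9 alternatives lost. Between these inhibitors 1872 genes were called, 860 higher and 1012 lower with importazole.

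The inhibitor groups were also compared with unstimulated cells, to ask how far each brought levels back to those without the hormone. No group had an inhibitor without endothelin-1. A return of the hormone's effect therefore cannot be told from an effect of the inhibitor on levels in unstimulated cells. Each inhibitor was given at a single dose, and the doses differed. With verapamil, ACTA1 was lower than without the hormone (-1.34 ± 0.21, adjusted p = 3.98e-04), as was MYH7 (-0.74 ± 0.10). NPPB (-0.54 ± 0.20), NPPA (0.10 ± 0.08), XIRP1 (0.13 ± 0.10), ANKRD1 (-0.35 ± 0.16), MYH6 (-0.11 ± 0.14), EDNRA (-0.38 ± 0.14) and RCAN1 (-0.06 ± 0.21) did not differ by the test. ACTA1 was lower than in unstimulated cells with importazole (-1.14 ± 0.21), higher with IPA-3 (1.18 ± 0.21) and stood at -0.03 ± 0.21 with ivermectin. Between inhibitors it was lower with importazole than with IPA-3 (-2.32 ± 0.21) and lower with verapamil than with ivermectin (-1.31 ± 0.21). NPPB stayed higher than in unstimulated cells with importazole (0.95 ± 0.20) and ivermectin (1.29 ± 0.20) and stood at 0.41 ± 0.20 with IPA-3. NPPA was higher with importazole (0.75 ± 0.08) and ivermectin (1.01 ± 0.08) and lower with IPA-3 (-0.37 ± 0.08), though at 0.76 there after quantile normalization. MYH7 was lower with importazole (-1.05 ± 0.10), IPA-3 (-1.93 ± 0.10) and ivermectin (-0.77 ± 0.10). XIRP1 was higher with IPA-3 (0.85 ± 0.10) and did not pass with importazole (0.25 ± 0.10) or ivermectin (-0.02 ± 0.10).

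Against unstimulated cells 367 genes were called with verapamil, 225 higher and 142 lower, a higher share of 61.3% that became 45.9% with median centring. The counts were 4825 with importazole (2393 higher), 6187 with IPA-3 (3079 higher) and 5214 with ivermectin (2607 higher). Of 26 lists camera called 11 with verapamil (6 with an estimated correlation), 11 with importazole (5), 11 with IPA-3 (10) and 8 with ivermectin (4). Of the 578 genes that endothelin-1 raised, 38 were still called higher than in unstimulated cells with verapamil, 246 with importazole, 362 with IPA-3 and 282 with ivermectin, and 35, 59, 49 and 60 were called lower. Of the 1213 that it lowered, 32, 548, 754 and 502 were still called lower and 33, 97, 74 and 113 were called higher. Both calls use the same unstimulated libraries, and no such counts were computed for unchanged groups.

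Genes that endothelin-1 raised were chosen in one part of the vehicle and unstimulated libraries and the return was measured in the rest, over 36 ways of splitting them. For raised genes, verapamil returned 101.2% of the change on average (range 96.4 to 106.0), importazole 70.9% (66.4 to 85.2), ivermectin 52.9% (48.5 to 63.0) and IPA-3 26.0% (21.5 to 42.5). For lowered genes, the shares were 90.3% with verapamil (84.2 to 98.2), 33.4% with ivermectin (25.3 to 39.7), 32.5% with importazole (22.6 to 39.6) and -18.3% with IPA-3 (-28.4 to -8.9). Measured as a median ratio the ranges over the same choices were wider, for lowered genes 84.8 to 107.2% with verapamil, 5.6 to 83.7% with ivermectin, 9.5 to 87.7% with importazole and -54.0 to 24.4% with IPA-3, and for raised genes 87.5 to 109.5%, 24 to 77.0%, 42.3 to 89.1% and -21.1 to 42.2%. With IPA-3 both of these ranges include 0. The hormone raised and all 4 inhibitors lowered 126 genes, and 186 genes went the opposite way. The vehicle libraries enter all 5 comparisons, which by itself favours such counts, and no value with split libraries was computed for them.

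**Figure D3:**
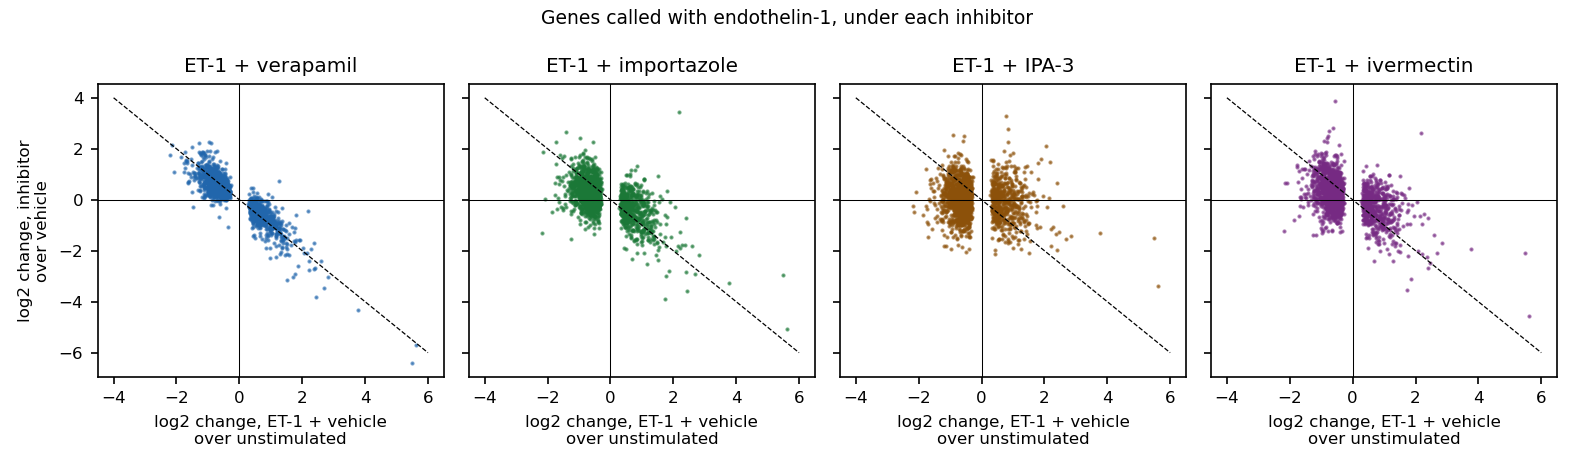
Log2 change of each of the genes called with endothelin-1 (horizontal axis, vehicle over unstimulated) against its log2 change with each inhibitor (vertical axis, inhibitor over vehicle); points are genes, and the dashed line marks a full return. The points share the vehicle libraries on both axes. For raised genes the return, measured in libraries not used to choose the genes, averaged 101.2% with verapamil and 26.0% with IPA-3. Vehicle libraries were still shared by both sides of that measure.

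Both sides of these overlaps use the vehicle libraries. Endothelin-1 raised and verapamil lowered 386 genes, against 30.6 for independent lists. With the vehicle libraries split between the sides the overlap was 226.3, against 12.7 for independent lists. For importazole the overlap was 301 (independent 79.4; split 176.3 against 34.2), for ivermectin 270 (independent 94.6; split 148.0 against 42.8) and for IPA-3 222 (independent 102.0; split 115.0 against 48.1). Among genes that endothelin-1 lowered, verapamil raised 780 (independent 159.4, split 313.2 against 51.3), importazole 497 (independent 274.3, split 203.7 against 110.3) and ivermectin 592 (independent 320.4, split 242.2 against 127.8). IPA-3 raised 345 of them (independent 315.0), and with split libraries 118.3, fewer than the 132.1 of independent lists. With split libraries importazole and IPA-3 shared 1423.5 higher genes (independent 456.0) and 720.8 lower genes (171.0). Importazole and ivermectin shared 1338.7 (440.3) and 771.0 (151.8) in this way, and IPA-3 and ivermectin 1376.8 (527.8) and 834.0 (214.2). Pairwise tests called 2530 genes between importazole and IPA-3, 3306 between IPA-3 and ivermectin, and 4413, 5782 and 4952 between verapamil and importazole, IPA-3 and ivermectin.

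Camera called 8 lists with endothelin-1, 14 with verapamil, 14 with importazole, 12 with IPA-3, 9 with ivermectin and 7 between importazole and ivermectin. Of these 7, 11, 10, 10, 8 and 4 held with an estimated correlation. The median, the mean and the test of a list had the same sign in all 64 of these calls and differed in sign in 21 of the 92 list tests that camera did not call. For verapamil against unstimulated cells, the smooth muscle and pericyte list had a median of 0.01 while camera's direction was down. Counts adjusted over the list alone moved by at most 4 genes. Adjusted over the list alone, endothelin-1 raised 15 immediate early genes and lowered 1, raised 6 sarcomere and 11 cytoskeleton genes and lowered 12 calcium handling genes. With verapamil 19 immediate early genes fell, 19 ATF4 targets, 13 cell cycle genes, 5 sarcomere genes, 5 smooth muscle markers and 1 heat shock gene rose, the cytoskeleton list had 4 up and 10 down, 3 oxidative phosphorylation genes fell and 2 endothelial markers fell. With importazole 2 fetal, 11 cholesterol and 6 oxidative phosphorylation genes rose, and 19 cytoskeleton genes and 3 endothelial markers fell. With IPA-3 17 fetal, 21 sarcomere, 12 fatty acid oxidation and 21 cholesterol genes fell and 26 ATF4 targets rose. With ivermectin 3 sarcomere genes rose, and the cytoskeleton list had 3 up and 23 down. Between importazole and ivermectin the counts higher were 8 for oxidative phosphorylation, 10 for glycolysis, 12 for reticulum chaperones, 14 for heat shock and 9 for lysosome genes, and 26 ATF4 targets were lower. The other counts of the called lists were the same.

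Lists that camera called in none of these 6 comparisons were the p53, aryl hydrocarbon receptor, inflammatory, interferon and pluripotency lists. Of 19 p53 targets, 8 rose and 3 fell with ivermectin (adjusted p = 0.129). Of 5 aryl hydrocarbon receptor targets, 1 rose with endothelin-1 (adjusted p = 0.105), and of 12 inflammatory genes 3 rose and 3 fell with it (adjusted p = 0.632). Of 9 interferon response genes, 4 rose and 1 fell with verapamil (adjusted p = 0.161), and of 6 pluripotency markers 1 rose with ivermectin (adjusted p = 0.365). The hepatic and endoderm list had only 2 tested genes and was not tested. The unstimulated and vehicle groups did not overlap for 2536 of the 12943 tested genes, where chance alone gives 2.86% of genes.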

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

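Chosen after the results were seen were the tests on the genes that rose under 3 inhibitors, the depth and GC tests on ATF4 targets, the test of reads shared between chemokine genes, the comparison of list medians over splits and the genes searched for outlying libraries, while the counts over splits, the axis test on ATF4 targets and the myeloid test were written down before their results were seen.

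Each level printed per group and 4 measures per library were searched for a library far from the other 3 of its group, in 90 groups. There were 8 such values in 6 libraries, where chance gives about 1 in 20 groups, or 4.5. NPPA was 37186 CPM in ivermectin replicate 4 against 33244 to 33574 in the others. CCL3L3 was 5.2 CPM in unstimulated replicate 4 against 8.74 to 9.41, and 4.93 CPM in verapamil replicate 3 against 3.15 to 3.45. HSPA6 was 242 CPM in verapamil replicate 3 against 140 to 154, and ACAT2 was 269 CPM in importazole replicate 3 against 304 to 311. Vehicle replicate 2 held 12292221 reads against 2141655 to 3750914, and verapamil replicate 4 had 11.1% of its reads in its 10 highest genes against 11.7 to 11.8%. The slope of levels on GC content was -0.169 log2 per 10 points in importazole replicate 3 against -0.083 to -0.072. NPPA no longer passed between importazole and ivermectin without ivermectin replicate 4 (-0.22), and the other calls of NPPA, CCL3L3 and ACAT2 checked without these libraries were the same. HSPA6 was not checked without verapamil replicate 3.

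A set of 252 genes was called at least 2-fold higher with importazole, IPA-3 and ivermectin alike, each against the same vehicle libraries, with median changes of 1.65, 1.62 and 1.30 against -0.22 with endothelin-1 and 0.33 with verapamil. It held EXOC5, EIF2S2 and 13 ATF4 targets, and its transcripts had a median GC content of 41.7% against 48.5% for all tested genes. With the GC trend of each library removed the set's median change was 1.34 ± 0.18 against 1.55 before, and after thinning to equal depth 1.58 ± 0.23, so neither accounts for most of it. The set moved along the axis that separates replicates within groups (slope 0.15 within groups), yet its mean over vehicle adjusted for that axis was 1.42 ± 0.14 against 1.62. The GC content was that of whole transcripts, and that of the amplicons themselves was not tested. A part from amplification by GC or from that axis may remain, and a shared response to inhibitors stays open as a hypothesis, since pool membership is not known.

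All 29 tested ATF4 targets rose with ivermectin, the group with the lowest median depth, with a median of 2.02. The median was 2.0 ± 0.12 with reads thinned to equal depth and 1.93 ± 0.07 with the GC trend removed. Their mean was 2.41 ± 0.10 adjusted for the axis of the replicates against 2.25 before. Each value lies above the 1.01 or 1.13 set as a bound, so depth, GC content of the transcripts and that axis do not account for most of the rise. Other technical sources, among them the GC content of the amplicons themselves, were not tested. A response of the cells to the inhibitor may explain the rise, as a hypothesis, with a difference between pools untested.

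CCL3, CCL3L3 and CCL4 rose with endothelin-1, and these chemokines are also products of myeloid cells. In vehicle libraries the abundant myeloid transcripts TYROBP, FCER1G, LAPTM5, CD74 and LYZ had a median of 0.0922 CPM and at most 0.895 CPM, below 33.3, which is 0.1 of the lowest CCL3L3 level in a vehicle library, so myeloid cells are an unlikely source. The ratio of CCL3 to CCL3L3 reads was 0.078 with vehicle and 0.055 with importazole (exact permutation p = 0.143, 2-sided, over 70 splits), so in this test reads shared between the copies cannot be told apart from a level of CCL3 itself. In unstimulated libraries the ratio was 0.186 (0.125 to 0.333), apart from the 0.068 to 0.092 of vehicle libraries, which goes against a constant ratio but rests on 16 reads of CCL3. A response of the cells to the hormone stays open as a hypothesis.

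Other splits of the same 8 libraries were refitted for each comparison, 35 with the real one. Mixed splits put the difference between the groups into the spread, so few calls are expected there. A difference between pools or cultures would look the same. In all 10 comparisons 1 split, the real one, called as many genes. As 1 of 35 is the smallest share possible, this argues against chance for each count but cannot exclude it. Among the other splits the highest count was 1 against 1791 with endothelin-1, 5 against 2386 with verapamil, 16 against 4705 with importazole, 18 against 5644 with IPA-3 and 559 against 5538 with ivermectin. Against unstimulated cells it was 2 against 367 with verapamil, 688 against 4825 with importazole, 11 against 6187 with IPA-3 and 1219 against 5214 with ivermectin, and between importazole and ivermectin it was 238 against 1872. For the number of lists called by camera, chance is not excluded. As many lists or more came from 3 of the 35 splits with endothelin-1 (real 8, highest other 9), 2 with verapamil (14 and 14), 3 with importazole (14 and 14), 6 with IPA-3 (12 and 13), 12 with ivermectin (9 and 11) and 7 between importazole and ivermectin (7 and 10). Camera ranks a list against the other genes of the same split. Splits that exchange 1 library between the groups keep part of the real difference, so they can call lists too. The sizes were compared as well, but for the same reason a smaller median in a mixed split is expected. Neither comparison settles chance for the lists. In 55 of the 64 list calls no other split gave a median as far from 0, among them ATF4 targets with ivermectin (2.02, highest other 1.20), and in 9 at least 1 other split did. Those 9 were the sarcomere and neural lists with endothelin-1, the heat shock, cytoskeleton, smooth muscle and neural lists with verapamil, the cholesterol and neural lists with importazole, and the chaperone list between importazole and ivermectin.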

How the results depend on the processing

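The tests with edgeR, DESeq2, thinned reads, GC correction, the replicate axis removed or its highest libraries left out were chosen after the results were seen. Of 273 gene results 248 kept their call under each alternative run, and those of them that were called kept their direction. A result that passed in neither fit was counted as the same whatever its sign. Of 6548 checks 6440 were the same, 71 no longer passed, 35 newly passed and 2 reversed. The 2 were NPPA with IPA-3 after quantile normalization, 0.37 against vehicle and 0.76 against unstimulated, where the cause was not tested. Counts of called genes stayed within 1.5 times except for verapamil against unstimulated, main 367, with 554 by array weights, 240 thinned and 635 with the replicate axis removed, and importazole against ivermectin, main 1872, with 1151 thinned. Thinning removes reads, and for the other 2 the cause was not tested. Leaving out 1 library gave 241 to 323 for verapamil against unstimulated, with 241 without unstimulated replicate 2 and 244 without unstimulated replicate 3. It gave 1310 to 1600 with endothelin-1, 1880 to 2067 with verapamil, 3881 to 4707 with importazole, 4957 to 5322 with IPA-3, 4722 to 5484 with ivermectin, 3936 to 4746, 5627 to 5991 and 4482 to 5197 for importazole, IPA-3 and ivermectin against unstimulated, and 1358 to 1764 between importazole and ivermectin. Lists called moved by over 1.5 times with fry, 21 with IPA-3, 19 with ivermectin and 16 between importazole and ivermectin, and against unstimulated cells 18 with importazole, 22 with IPA-3 and 15 with ivermectin (main 11, 11 and 8), since fry does not compare a list with other genes. Between importazole and ivermectin they were also 4 with an estimated correlation, 12 with no filter and 11 thinned, where the cause was not tested. Leaving out 1 library gave 8 to 9 lists with endothelin-1, 13 to 14 with verapamil and with importazole, 11 to 14 with IPA-3, 9 to 10 with ivermectin and 7 to 10 between importazole and ivermectin. The share returned of genes that endothelin-1 lowered also moved. With a median ratio it was 37.9% for importazole, -23.4% for IPA-3, 41.0% for ivermectin and 95.7% for verapamil, and with genes at an adjusted p under 0.01 it was -24.4% for IPA-3. GC-corrected it was 27.1%, -30.0%, 24.5% and 85.8%, and with the replicate axis removed 38.1% for importazole, -11.1% for IPA-3 and 38.9% for ivermectin, where the cause was not tested. Of these only 41.0% and 24.5% for ivermectin and -30.0% for IPA-3 lie outside the range of the slope over the 36 choices of libraries. The 41.0% is a median ratio and lies inside the range of that measure, 5.6 to 83.7%. With the replicate number as a block the counts were 1704 with endothelin-1, 2286 with verapamil, 4604 with importazole, 5563 with IPA-3 and 5483 with ivermectin, and 273 of the 273 gene results and each list count were the same. The numbers do not pair the samples, since 4 of 24 libraries correlated best with their own number. The settings fixed beforehand for deposited counts, which were other size factors and limma-voom, were not run because the files hold CPM. Depth limits genes near 1 CPM, where the smallest library gives 1.49 reads.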

Other observations

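The groups of genes in this part and the tests on them were chosen after the results were seen. Aminoacyl-tRNA synthetases of the cytosol, which load amino acids onto tRNAs, rose for 14 of 20 genes with ivermectin and fell for 1. WARS rose by 2.12 ± 0.17 (limma adjusted p = 9.01e-12), MARS by 2.11 ± 0.12 and YARS by 1.80 ± 0.12. They rose for 14 of 20 with importazole, none fell, and for 14 with IPA-3, 2 fell, with medians of 0.57, 0.90 and 0.83 for importazole, IPA-3 and ivermectin. MARS rose less with importazole than with ivermectin (-1.19 ± 0.12 between them). With endothelin-1 alone 1 rose and 1 fell, and with verapamil 6 rose. Of the 20 genes 4 were also ATF4 targets in the fixed list. Among 16 mitochondrial synthetases 2 rose and 6 fell with ivermectin.

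Fatty acid synthesis genes differed between importazole and ivermectin, the only pair of inhibitors in which this group was tested. Of 11 genes 7 rose and none fell with importazole, 1 rose and 6 fell with IPA-3, and 3 rose and 6 fell with ivermectin. The desaturase SCD was at 0.87 ± 0.11, -1.17 ± 0.11 and -0.94 ± 0.11 in these groups and FADS2 at 0.53 ± 0.11, -1.04 ± 0.11 and -0.70 ± 0.11. With verapamil 4 rose, among them SCD by 0.42 ± 0.11 and FADS2 by 0.52 ± 0.11, and 1 fell. Between importazole and ivermectin SCD was higher by 1.80 ± 0.11 and FASN by 1.27 ± 0.14, and 8 of the 11 were higher. Camera's unadjusted p for that contrast was 1.07e-14 and 5.09e-05 with an estimated correlation. Histone genes fell for 17 of 54 with endothelin-1 and none rose, HIST1H3B by -1.10 ± 0.24 and HIST1H2AC by -0.75 ± 0.12, and 22 rose and none fell with verapamil, HIST1H3B by 1.75 ± 0.24. Both comparisons use the same vehicle libraries, and against these 20 histone genes also rose and 3 fell with ivermectin, and 13 rose and 5 fell with importazole and the same with IPA-3. Camera's p for histone genes was 2.45e-07 and 2.1e-07 with endothelin-1 and verapamil and 0.00305 and 0.00292 with an estimated correlation.

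The rise of cytosolic synthetases may be separate from protein synthesis genes at large. Outside the ATF4 list 16 of them had a median of 0.63 with ivermectin, against -0.19 for the mitochondrial ones (permutation p = 4e-04, 1-sided, by permutation of the genes) and 0.02 for 74 cytosolic ribosomal proteins, of which 20 rose and 21 fell. Whether these 16 are ATF4 targets missing from the fixed list was not tested, so their rise is not set apart from that of ATF4 targets. Genes are not independent replicates, and the groups were found in these data, so a rise apart from other protein synthesis genes is a hypothesis.

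A change in the number of cycling cells could move histone genes. The fixed cell cycle list had a camera adjusted p of 0.364 with endothelin-1, median -0.20, and of 5.05e-04 with verapamil, where 10 of 22 rose. The first does not pass the threshold and does not show that cycling was unchanged, so this stays open. Proteasome subunits and metallothioneins were looked at too. Of 36 proteasome subunits 15 rose and 4 fell with IPA-3 and 7 rose and 12 fell with ivermectin, and of 5 metallothioneins 2 rose with IPA-3.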
